A study of Mus musculus with 14 samples.

How the data were processed

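RNA was sequenced from mouse corpus callosum (4 libraries labelled WT and 4 labelled Qk-KO) and from oligodendrocytes differentiated in culture from neural stem cells (3 libraries labelled WT and 3 labelled Qk-KO), and each system has its own deposited table. The submitters' processing notes name FastQC, TopHat2 2.0.14, featureCounts and DESeq2 with the genome build mm10, without their settings. The gene annotation, the strand setting of the counting and the model design are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Each table has 46983 genes by versioned Ensembl identifier with a symbol.

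The library columns of both tables hold log2 values that the authors deposited, and a check of the values showed what they are. Within a genotype, the libraries differ from each other by 1 constant factor at every gene, within 1e-09 on the log2 scale. Between genotypes they differ by the deposited log2 fold change plus a constant, within the same tolerance. The columns are therefore the log2 of a model's fitted mean plus 1, and they carry no spread between replicates. A model term that differs between libraries of a genotype, such as passage, would break the constant factor. The fitted means therefore hold genotype as their only term. The mean column is a normalized signal, the average over libraries of counts divided by size factors, per the file headers. The deposited log2 fold change and its standard error are on a log2 scale, and the direction in both tables is WT over Qk-KO, so every value was turned to labelled Qk-KO minus WT. The deposited score is the fold change divided by its standard error, checked within the same tolerance. The deposited p-value columns hold a p-value per gene and its Benjamini-Hochberg adjusted value, and recomputing the adjustment over the genes that carry one returned the deposited values within 1e-06. The authors used DESeq2, per the submitters' processing notes, and the column names are those of its output. Fold changes of genes with few reads lie close to 0, with absolute log2 values up to 1.06 in callosum and 0.96 in culture at means under 1, and standard errors have a ceiling of 0.54 and 0.76, which is how values shrunken toward 0 look. Folds of genes with low counts may therefore be understated.

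Depth was read from the fitted counts summed per library, between 15048646 and 27666519 in callosum and between 38325833 and 48912999 in culture. These sums are of model means, not of the reads themselves. The gene mt-Rnr2 took 18.4% of the mean normalized counts in culture and 4.35% in callosum. Genes without reads (14022 in callosum, 18424 in culture) have no fold change, and genes below a mean of 8.08 in callosum or 8.52 in culture have no adjusted p. A fold change without any p-value stands for 156 genes in callosum and 20 in culture. The tested genes number 19935 in callosum and 17503 in culture.

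The design fixed before the data were examined was a quasi-likelihood test on counts, or limma on log2 values, but neither was run, because fitted means carry no replicate spread and such a test would return a meaningless result. No single library could be examined for outlying values either. All gene calls therefore rest on the deposited statistics, at an adjusted p under 0.05 with no minimum fold. Fitted CPM (a gene's share of the library's fitted counts, on the usual CPM scale) was computed from these columns. Gene lists (35, fixed before the data were examined) were tested with camera in its pre-ranked form (limma 3.58.1, R 4.3.3) on the deposited score, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, for lists with at least 5 tested members. The pre-ranked form took the place of the planned one after the columns had been examined. No correlation between genes could be estimated from these columns, so presets of 0.05 and 0.1 stand in for it, and the self-contained test fry was not run. The difference between the systems was tested with a z test on the 2 deposited log2 fold changes and their standard errors, over the 16601 genes tested in both tables. Overlap of calls was tested with Fisher's exact test, two-sided, for each pair of directions. The tables were normalized separately, so levels were not compared between them.

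Some genes of the closing parts, and those marked as named or chosen after their values were seen, lie outside the naming rule. The other genes named in the text follow a rule fixed before the data were examined. It takes Qk; the 8 highest and 8 lowest called genes per comparison with at least 5 CPM, leaving out sex-linked genes, predicted models and pseudogenes; members of each called list or list with at least 3 called members (4 with the smallest p and 1 that did not pass); fixed myelin genes, among them Mbp, Mog and Mag; the 5 genes with the strongest difference between systems; 6 genes called in both per direction; and the 2 most abundant members of lists for other cell types. The sex-linked genes left out were those that follow the animals' sex (Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty), so other X-linked genes could be named. The rule's condition that genotypes do not overlap between libraries could not be applied. Some genes that the rule selects are not reported here. Coordinates come from GENCODE mouse release 21 on GRCm38, the assembly that mm10 names; 46488 of the 46983 identifiers matched it without their version, and 37902 with the same version.

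The steps were tested on simulated effects of known size with the real standard errors (Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1). In the callosum simulation over 19929 genes, 71% of 100 genes changed by 1 log2 unit and 96% of 100 changed by 2 were called. In the culture simulation over 17497 genes, these shares were 55% and 87%. For the difference of both systems over 16596 genes, they were 50.6% and 83.8%. The simulation changed 200 genes per system, while 5003 were called in the real culture data, so its shares need not hold there. Its noise followed the normal reference that the test used, so it cannot speak to the choice of reference. The simulated effects were entered at full size, while the deposited fold changes look shrunken, which the simulation left out. The shares called in the simulation may therefore be too high, above all for genes with few reads. Alternatives tried were other thresholds, filters, scalings, a heavier-tailed reference for the score, and other settings of the set test.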

Results

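RNA-seq profiles were compared between libraries labelled Qk-KO and libraries labelled WT in mouse corpus callosum and in cultured oligodendrocytes. Qk encodes the RNA-binding protein quaking, which is abundant in myelinating glia. For the tissue, mice of a mixed FVB and C57BL/6 background with a tamoxifen-inducible Cre recombinase received tamoxifen at 8 weeks of age, and the callosum was taken 4 days later. The 4 animals labelled Qk-KO had both Qk copies floxed, and the 4 labelled WT had 1 floxed copy, so the controls are not free of the floxed allele. For the culture, neural stem cells at passages 7, 12 and 13 were differentiated with 100 ng/ml IGF-1 and 50 ng/ml triiodothyronine, with 3 libraries per genotype. The sample descriptions carry 40HT for every culture labelled Qk-KO and EtOH for every culture labelled WT, so treatment and genotype coincide there. Fitted counts summed to between 15048646 and 27666519 per callosum library and between 38325833 and 48912999 per culture library. The columns for single libraries hold fitted means without replicate spread, so values are given per genotype, with the standard errors of the authors' deposited table.

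The targeted gene did not show lower total expression in either system. Qk (ENSMUSG00000062078.14, chromosome 17, 10202601 to 10319854, minus strand, GRCm38) had a log2 change of 0.32 ± 0.12 (SE) in callosum, with an adjusted p of 0.162 in the authors' deposited table. Its fitted level was 713 CPM in WT and 907 CPM in libraries labelled Qk-KO. In culture, Qk rose by 0.66 ± 0.14 log2 units (adjusted p = 4.19e-05, authors' deposited table), from 1972 to 3277 CPM. These values go against a simple loss of Qk RNA. They cover reads over the whole gene, including parts outside a floxed segment, so they check neither the deletion nor the labels.

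In the corpus callosum, genes of activated microglia, the resident macrophages of the brain, rose in libraries labelled Qk-KO. Itgax, the integrin CD11c, rose 50.3-fold (log2 5.65 ± 0.34, adjusted p = 2.3e-59, authors' deposited table), from 0.363 to 18.5 CPM. Clec7a, a pattern-recognition receptor, rose by 4.79 ± 0.31, Cst7, a cysteine protease inhibitor, by 4.06 ± 0.31, and the chemokine Ccl6 by 3.66 ± 0.28 log2 units in the authors' deposited table. Lyz2 (2.62 ± 0.21), the acute-phase gene Serpina3n (2.38 ± 0.14), Tyrobp (2.24 ± 0.19), Myo1f (2.18 ± 0.24) and the complement receptor C3ar1 (2.15 ± 0.25) followed in the authors' deposited table. Falls were fewer and smaller. Tnnt1 fell by 1.65 ± 0.38, Serpinb1a by 1.30 ± 0.18, Anln by 1.22 ± 0.21, Mctp2 by 1.15 ± 0.35, Cldn2 by 1.04 ± 0.32 and Pls1 by 1.03 ± 0.21 log2 units in the authors' deposited table. The standard errors of Tnnt1, Mctp2 and Cldn2 are well above the median of 0.19 over the tested genes. Whether uneven amounts of neighbouring tissue, taken up in the last part, lie behind these falls was not tested. Of 19935 tested genes, 463 passed an adjusted p under 0.05, with 417 higher and 46 lower, and 190 of them changed at least 2-fold. With a Student reference for the score in place of the normal one, 8 passed.

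Of the 22 tested microglia markers, 16 rose and none fell (18 adjusted over the list alone), with a list median of 1.01 log2 units and a camera adjusted p of 2.06e-67. Tyrobp, Trem2 (1.98 ± 0.23) and the protease Ctss (1.45 ± 0.17) were among those with the smallest p, and Csf1r, the receptor for microglial survival factors, rose by 0.87 ± 0.16 in the authors' deposited table. Itgam did not pass (0.74 ± 0.29, adjusted p = 0.265) in the authors' deposited table. P2ry12 (0.18 ± 0.13) and Tmem119 (0.10 ± 0.15), named after their values were seen, did not pass either in the authors' deposited table. Of the 22 activated microglia genes, 20 rose and none fell (21 adjusted over the list alone), with a median of 1.70 and a camera adjusted p of 7.51e-151. Apoe, a lipid carrier, rose by 0.74 ± 0.15, while the ferritin gene Fth1 stood at 0.54 ± 0.17 with an adjusted p of 0.0539 in the authors' deposited table. Lysosome and endosome genes rose in 7 of 32 cases (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.12e-06). The protease genes Ctsd (1.19 ± 0.14) and Ctsz (1.42 ± 0.19), Gusb (0.94 ± 0.13) and Hexa (0.58 ± 0.13) led them in the authors' deposited table. Tfeb, a regulator of lysosomal genes, had 0.64 ± 0.21 and an adjusted p of 0.076 in the authors' deposited table. The list median was 0.04, and the rank version of the set test gave an adjusted p of 0.0641. Cholesterol efflux genes rose in 3 of 14 cases (6 adjusted over the list alone; camera adjusted p = 5.06e-04). They were Apoe, Ch25h (1.56 ± 0.39) and Abca2 (0.39 ± 0.12), with Abca1 at 0.51 ± 0.18 and an adjusted p of 0.151 in the authors' deposited table. Apoe and Ch25h are also members of the activated microglia list.

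Oligodendrocyte genes moved in both directions in callosum. Among 17 myelin protein genes, 5 rose and none fell (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 6.78e-09). Mog rose 2.18-fold (log2 1.12 ± 0.15, adjusted p = 1.81e-11), Opalin by 1.16 ± 0.16, Mag by 0.94 ± 0.17 and the tetraspanin Cd9 by 0.88 ± 0.14 in the authors' deposited table. Mbp (0.14 ± 0.16), which encodes an abundant myelin protein, did not pass, nor did Mal (-0.48 ± 0.16) in the authors' deposited table. Of 30 mature oligodendrocyte markers, 7 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.00206, higher, and 0.147 at a preset correlation of 0.1). Gsn, an actin-severing protein, rose by 1.88 ± 0.21 and Myrf, a transcription factor of myelin genes, by 1.09 ± 0.17, while Anln and Ndrg1 fell by 1.22 ± 0.21 and 0.93 ± 0.16 in the authors' deposited table. Plekhh1 had 0.42 ± 0.16 (adjusted p = 0.226) in the authors' deposited table. Of 14 newly formed oligodendrocyte markers, 2 rose (3 adjusted over the list alone; camera adjusted p = 6.86e-05). Bcas1 rose by 0.90 ± 0.23 and Mpzl1 by 0.54 ± 0.15, with Gpr17 at 0.55 ± 0.18 and an adjusted p of 0.0773 in the authors' deposited table. Of 18 precursor markers, 1 rose (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.192). This was Lims2 (0.65 ± 0.19, authors' deposited table), named after its value was seen.

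Lipid synthesis genes fell in the callosum in a few cases. In the list for fatty acid synthesis, elongation and desaturation, 2 of 35 rose and 2 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.00835, lower, and 0.291 at a preset correlation of 0.1). The desaturase genes Scd2 and Scd1 fell by 0.38 ± 0.09 and 0.48 ± 0.13 log2 units, while Fa2h (0.59 ± 0.16) and Elovl1 (0.48 ± 0.14) rose in the authors' deposited table. Acss2 did not pass (-0.26 ± 0.09) in the authors' deposited table. Of 21 cholesterol biosynthesis genes, 1 fell (5 adjusted over the list alone; camera adjusted p = 0.00278, lower, and adjusted p = 0.119 at a preset correlation of 0.1). This was Idi1 (-0.35 ± 0.10), and Msmo1 had -0.30 ± 0.10 with an adjusted p of 0.076 in the authors' deposited table. Of 23 sphingolipid genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), without a call for the list (camera adjusted p = 0.893). Fa2h and Gal3st1 (0.60 ± 0.18) rose, Degs1 fell by 0.38 ± 0.09, and Sgms1 stood at -0.25 ± 0.12 in the authors' deposited table. No gene of fatty acid beta-oxidation (32), peroxisome biogenesis (20) or the PPAR and RXR receptors (10) passed, over all genes or adjusted over the list alone. Of 29 PPAR target genes, 1 rose (2 adjusted over the list alone), as did 1 of 32 phospholipid genes (1), and 1 of 14 SREBP regulation genes fell (2). These were Lpl (0.72 ± 0.18), Lpcat2 (0.59 ± 0.17) and Insig1 (-0.50 ± 0.13), chosen after their values were seen in the authors' deposited table. None of these 6 lists passed the set test, with camera adjusted p values from 0.251 to 0.97.

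Markers of other cell types gave few single calls in callosum. Of 19 astrocyte markers, 2 rose (2 adjusted over the list alone), and the list, with a median of 0.00, did not pass (camera adjusted p = 0.11). The intermediate filament gene Gfap rose by 2.06 ± 0.19 (4.16-fold) in the authors' deposited table. The water channel gene Aqp4, named after its value was seen, rose by 0.69 ± 0.18. The abundant Slc1a2 and Aldoc had 0.10 ± 0.16 and -0.03 ± 0.08 in the authors' deposited table. No neuron marker passed, though 17 of 18 values were negative (median -0.14; camera adjusted p = 0.00409, and 0.119 at a preset correlation of 0.1). Among the most abundant, Snap25 had -0.18 ± 0.17 and Map2 -0.07 ± 0.13, and Nefl had -0.34 ± 0.15 in the authors' deposited table. The ependymal and choroid plexus list was lower (median -0.60; camera adjusted p = 0.0012) with no member past the threshold. The choroid plexus genes Ttr, Kl and Folr1 had -0.81 ± 0.38, -0.86 ± 0.38 and -0.82 ± 0.31, but the ependymal genes Foxj1 and Ccdc153, named after their values were seen, had -0.01 ± 0.29 and 0.06 ± 0.37 in the authors' deposited table. Mitochondrially encoded genes were lower as a list (median -0.19; camera adjusted p = 5.06e-04), with 14 of 14 negative values. The gene mt-Atp8 had -0.30 ± 0.11 in the authors' deposited table. Endothelial and mural markers had a median of -0.10 (camera adjusted p = 0.0471, and 0.302 at a preset correlation of 0.1). Rgs5 had -0.20 ± 0.08 and Slco1a4 -0.16 ± 0.13 in the authors' deposited table. Blood, fibroblast, cortical and striatal lists (6, 12, 15 and 17 genes) had no member past the threshold, also adjusted over the list alone, and no set call (camera adjusted p from 0.223 to 0.959). Their most abundant members were Hbb-bs (0.17 ± 0.24), Hba-a1 (0.37 ± 0.25), Igf2 (-0.58 ± 0.25), Col6a1 (0.35 ± 0.39), Camk2a (-0.08 ± 0.19), Slc17a7 (0.00 ± 0.25), Pde10a (0.11 ± 0.46) and Gad1 (-0.03 ± 0.18) in the authors' deposited table. The lists for neural stem cells (17 genes; 1 higher and 2 lower adjusted over the list alone), cell cycle (27), interferon (19), immediate early genes (16), heat shock (17) and splicing proteins (20) had no member past the threshold over all genes. The stress response, p53 and QKI-bound lists had 1 of 23, 18 and 9 (1, 1 and 1 higher and, for QKI-bound, 1 lower adjusted over the list alone). These were Atf3 (1.78 ± 0.36), Phlda3 (0.71 ± 0.14) and Mag, the first 2 chosen after their values were seen in the authors' deposited table. None of these 9 lists passed the set test (camera adjusted p from 0.105 to 0.985). Median, mean and test differed in sign in some lists without a call, among them the cortical, stem cell, SREBP, receptor and QKI-bound lists. The test here is the authors' deposited Wald test with 4 libraries per genotype; it cannot be repeated without 1 of the libraries.

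In cultured oligodendrocytes, astrocyte, lipid oxidation and lysosomal genes fell in libraries labelled Qk-KO, and neuronal and cell cycle genes rose. Astrocyte marker RNA was abundant in these cultures. Fitted levels in cultures labelled WT were 4008 CPM for Gfap and 2408 CPM for Gja1, against 525 CPM for Mbp and 1077 CPM for Gpr17. The values therefore describe whole cultures, not oligodendrocytes alone. Cacng2, a neuronal calcium channel subunit, rose 61.2-fold (log2 5.94 ± 0.37, adjusted p = 1.2e-55, authors' deposited table), from 0.196 to 12.7 CPM. Actl6b (4.55 ± 0.25), the adhesion gene L1cam (4.29 ± 0.32), the splicing regulator Srrm3 (4.24 ± 0.20), the synaptic gene Snap25 (3.84 ± 0.23), Iqsec3 (3.82 ± 0.56), Sez6l2 (3.72 ± 0.23) and Slit1 (3.66 ± 0.33) followed in the authors' deposited table. The fatty acid transporter gene Cd36 fell by 5.14 ± 0.30 log2 units (adjusted p = 1.12e-63, authors' deposited table), from 10.1 to 0.301 CPM. The interferon-induced Ifit3, Ifit3b and Ifit2 fell by 4.90 ± 0.30, 4.83 ± 0.25 and 3.63 ± 0.16 in the authors' deposited table. Abhd3 (-3.85 ± 0.21), Tmem144 (-3.79 ± 0.34), Cldn10 (-3.61 ± 0.31) and Gjb6 (-3.57 ± 0.55) fell as well in the authors' deposited table. Ifit3 and Ifit3b are close copies, so the values of both are uncertain where reads were split between them. Of 17503 tested genes, 5003 passed, 2336 higher and 2667 lower. Scaling by library size alone turned this split to 3054 higher and 2296 lower. With a Student reference for the score, 0 genes passed in culture, Qk included.

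Astrocyte markers fell in 15 of 19 cases (17 adjusted over the list alone; median -1.24; camera adjusted p = 5.14e-22). Gfap fell by 3.37 ± 0.29, Mlc1 by 2.56 ± 0.13, Acsbg1 by 2.31 ± 0.22 and the gap junction gene Gja1 by 2.23 ± 0.15 in the authors' deposited table, while Aldoc had -0.39 ± 0.16 and an adjusted p of 0.0573. Neuron markers rose in 10 of 16 cases (10 adjusted over the list alone; median 1.14; camera adjusted p = 1.26e-09). Syn1 rose by 2.33 ± 0.28, the neuronal tubulin gene Tubb3 by 1.74 ± 0.19, Syp by 1.63 ± 0.21 and Map2 by 1.04 ± 0.20, and Gabrb2 had 1.19 ± 0.60 without passing in the authors' deposited table. Cell cycle genes rose in 16 of 28 cases (19 adjusted over the list alone; median 0.85; camera adjusted p = 7.24e-06). They included Mcm5 (1.60 ± 0.28), Ccne1 (1.44 ± 0.18), the proliferation marker Mki67 (1.24 ± 0.22) and Mcm6 (0.85 ± 0.18), and Tyms had 0.40 ± 0.17 in the authors' deposited table. Neural stem cell genes rose in 6 and fell in 2 of 17 cases (7 and 4 adjusted over the list alone) without a set call (camera adjusted p = 0.209). Hes5 rose by 1.49 ± 0.21, Fabp7 by 0.96 ± 0.17 and Nes by 0.61 ± 0.14, Msi1 fell by 0.91 ± 0.15, and Nr2e1 had -0.58 ± 0.24 in the authors' deposited table.

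Oligodendrocyte genes were mixed in culture. Of 16 myelin genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0783). However, 14 of the 16 values were negative, with a median of -0.53, and the rank version of the set test gave an adjusted p of 0.0434. Mal and Pmp22 fell by 2.61 ± 0.35 and 2.11 ± 0.27, Cd9 fell by 0.61 ± 0.17, and Mog and Opalin rose by 1.28 ± 0.52 and 1.49 ± 0.58 in the authors' deposited table. Mbp (-0.28 ± 0.63), Mag (-0.59 ± 0.71) and Omg (-0.54 ± 0.23) did not pass in the authors' deposited table, and the wide errors of Mbp and Mag limit what could be detected. Of 27 mature markers, 1 rose and 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.0102, lower, and 0.219 at a preset correlation of 0.1). Aspa (-2.14 ± 0.34), Car2 (-1.97 ± 0.24), Sept4 (-1.85 ± 0.24) and Plekhb1 (-1.41 ± 0.18) fell, and Carns1 had -0.67 ± 0.31 in the authors' deposited table. Of 18 precursor markers, 3 rose and 4 fell (3 and 6 adjusted over the list alone). Dpysl3 (1.31 ± 0.27) and the lineage factor Olig2 (0.81 ± 0.16) rose, Rlbp1 (-1.37 ± 0.20) and Ptprz1 (-1.02 ± 0.23) fell, and Emid1 had -0.65 ± 0.27 in the authors' deposited table. Of 15 newly formed markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone). Bmp4 (1.76 ± 0.27) and Tcf7l2 (0.49 ± 0.14) rose, Gpr17 fell (-0.45 ± 0.15), and Cnksr3 had 0.71 ± 0.29 in the authors' deposited table. Neither the precursor nor the newly formed list passed (camera adjusted p = 0.897 and 0.209).

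Fatty acid beta-oxidation genes fell in 26 of 32 cases and rose in none (26 adjusted over the list alone; median -0.77; camera adjusted p = 2.83e-17). Abcd3, a peroxisomal transporter, fell by 1.71 ± 0.13, Cpt1a, which controls entry of fatty acids into mitochondria, by 1.49 ± 0.13, Acadm by 1.21 ± 0.12 and Acadl by 2.05 ± 0.22 in the authors' deposited table, and Acaa1b had -0.52 ± 0.46. Of 29 PPAR target genes, 19 fell and 2 rose (20 and 2 adjusted over the list alone; camera adjusted p = 1.5e-09), and 7 of the list's genes also belong to beta-oxidation. Besides Cd36, Acadl and Cpt1a, Acaa2 fell by 1.41 ± 0.16, and Acot2 had -0.59 ± 0.27 in the authors' deposited table. The receptor genes Ppara, Rxra and Ppard fell by 1.40 ± 0.30, 0.56 ± 0.18 and 0.46 ± 0.15, Rxrg rose by 1.97 ± 0.37, and Ncoa2 had 0.28 ± 0.12 in the authors' deposited table. Of these 10 receptor and cofactor genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), without a call for the list (camera adjusted p = 0.885). In the fatty acid synthesis list, 15 of 35 fell and 6 rose (17 and 7 adjusted over the list alone; camera adjusted p = 1.39e-04, lower, and 0.0772 at a preset correlation of 0.1). Scd1 fell by 1.65 ± 0.14, Scd2 by 1.62 ± 0.13 and the elongase gene Elovl5 by 1.57 ± 0.16 in the authors' deposited table, and Acacb had -0.88 ± 0.36.

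Lysosome and endosome genes fell in 24 of 32 cases and rose in none (24 adjusted over the list alone; median -0.70; camera adjusted p = 1.03e-15). Galc, which degrades a myelin galactolipid, fell by 2.16 ± 0.16, Lamp1 by 1.66 ± 0.13, Asah1 by 1.38 ± 0.14 and the cholesterol transporter gene Npc1 by 1.38 ± 0.13 in the authors' deposited table, while Gusb had -0.32 ± 0.16. Cholesterol biosynthesis was split, with 3 of 21 higher and 3 lower (3 and 3 adjusted over the list alone) and no set call (camera adjusted p = 0.812). Hmgcs1 fell by 1.46 ± 0.16 and Sc5d fell by 0.61 ± 0.14, Ebp rose by 1.25 ± 0.24 and Acat2 by 0.49 ± 0.12, and Mvd had -0.52 ± 0.23 in the authors' deposited table. SREBP regulation genes were split as well (2 higher and 3 lower of 13, also adjusted over the list alone; camera adjusted p = 0.888). Soat1 (-1.49 ± 0.18) and Srebf1 (-1.30 ± 0.22) fell, Vldlr (0.68 ± 0.15) and Mylip (1.08 ± 0.21) rose, and Insig2 had 0.26 ± 0.18 in the authors' deposited table. Of 13 efflux genes, 5 fell and 3 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.0423, lower, and 0.219 at a preset correlation of 0.1). Abca1 (-1.85 ± 0.20), Cyp46a1 (-1.63 ± 0.27) and Apoe (-1.49 ± 0.20) fell, Abcg1 rose (1.40 ± 0.31), and Apod had -1.16 ± 0.62 in the authors' deposited table. Phospholipid genes fell in 10 and rose in 3 of 32 cases (12 and 4 adjusted over the list alone; camera adjusted p = 0.0102, and 0.219 at a preset correlation of 0.1). Chpt1 (-2.26 ± 0.18), Agpat3 (-1.80 ± 0.13), Gpam (-0.91 ± 0.12) and Pisd (-0.82 ± 0.15) fell, and Pemt had -0.71 ± 0.30 in the authors' deposited table. Peroxisome genes fell in 7 of 20 cases (7 adjusted over the list alone; camera adjusted p = 0.0267, and 0.219 at a preset correlation of 0.1). Pex7 (-1.52 ± 0.14), the catalase gene Cat (-0.90 ± 0.17) and Mpv17 (-0.80 ± 0.15) fell, as did Pxmp2 (adjusted p = 0.00108), in the authors' deposited table. Sphingolipid genes had 3 higher and 2 lower of 22, also adjusted over the list alone, and no set call (camera adjusted p = 0.922). Degs1 (-1.71 ± 0.16) and Cers1 (-0.86 ± 0.19) fell, Ugcg (1.13 ± 0.16) and Fa2h (0.73 ± 0.25) rose, and Acer3 had 0.27 ± 0.13 in the authors' deposited table.

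Heat shock, oxidative stress and interferon response genes were lower as lists in culture. Heat shock and oxidative stress genes fell in 10 and rose in 1 of 17 cases (11 and 3 adjusted over the list alone; camera adjusted p = 7.92e-05). The antioxidant gene Srxn1 (-2.17 ± 0.19), the metallothioneins Mt1 (-1.66 ± 0.18) and Mt2 (-1.21 ± 0.16) and Gclm (-1.50 ± 0.18) fell, and Dnajb1 had 0.42 ± 0.19 in the authors' deposited table. Interferon response genes fell in 6 and rose in 1 of 20 cases (6 and 1 adjusted over the list alone; camera adjusted p = 3.12e-05). Gbp3 (-1.26 ± 0.19) and Gbp2 (-1.44 ± 0.25) fell besides the Ifit genes, Mx1, named after its value was seen, rose (2.12 ± 0.57), and Ddx58 had -0.40 ± 0.18 in the authors' deposited table. Splicing proteins rose in 9 and fell in 1 of 20 cases (9 and 1 adjusted over the list alone; camera adjusted p = 0.00912, and 0.176 at a preset correlation of 0.1). Rbfox2 (1.53 ± 0.20), Hnrnph1 (0.90 ± 0.15), Khdrbs1 (0.58 ± 0.16) and Celf1 (0.47 ± 0.11) rose, and Khdrbs2 had 0.59 ± 0.28 in the authors' deposited table. The unfolded protein list had 5 higher and 3 lower of 24 (6 and 6 adjusted over the list alone), with Phgdh (-0.98 ± 0.16) and Psph (-0.81 ± 0.15) lower and Asns (0.66 ± 0.13) and Sdf2l1 (0.86 ± 0.19) higher in the authors' deposited table. The p53 list had 3 and 2 of 17 (4 and 2 adjusted over the list alone), with Plk2 (1.12 ± 0.21) and Mdm2 (0.62 ± 0.15) higher and Ccng1 (-0.96 ± 0.19) and Gadd45a (-0.80 ± 0.19) lower in the authors' deposited table. The immediate early list had 2 and 4 of 16 (2 and 4 adjusted over the list alone), with Dusp1 (1.06 ± 0.27) higher and Egr2 (-1.29 ± 0.31) lower in the authors' deposited table. Of 9 QKI-bound mRNAs, 1 was lower (0 adjusted over the list alone), and no mitochondrially encoded gene of 12 passed. These lists did not pass the set test, with camera adjusted p values from 0.465 to 0.922.

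Microglial genes were near the detection limit in culture, where 6 of 22 microglia markers were tested and 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0753). They included P2ry12 (-2.19 ± 0.41), Olfml3 (-0.92 ± 0.33) and Sall1 (-0.63 ± 0.17) in the authors' deposited table. Of 11 tested activated microglia genes, 6 fell (6 adjusted over the list alone; camera adjusted p = 6.12e-04). Axl (-1.77 ± 0.17), Apoe, Fth1 (-0.98 ± 0.18) and Csf1 (-0.80 ± 0.14), which other cells also express, fell, while Lyz2 had -0.89 ± 0.62 in the authors' deposited table. Cortical (4 higher and 1 lower of 9), striatal (4 and 2 of 11), endothelial (0 and 3 of 9), fibroblast (0 of 5) and choroid plexus lists (0 and 3 of 11) did not pass, with camera adjusted p values from 0.256 to 0.897. Adjusted over the list alone, these counts were 4 and 1, 4 and 3, 0 and 3, 0, and 0 and 4. Members past the threshold included Bcl11b (1.93 ± 0.27), Nptx1 (1.09 ± 0.26), Rorb (-0.95 ± 0.24), Pde10a (0.92 ± 0.21), Gad1 (0.86 ± 0.29), Pvalb (-1.76 ± 0.29), Rgs5 (-1.65 ± 0.40) and Foxj1 (-1.15 ± 0.25) in the authors' deposited table. Acta2 (1.38 ± 0.72), Ogn (1.32 ± 0.68), Fmod (-0.70 ± 0.41) and Folr1 (0.31 ± 0.41) did not pass in the authors' deposited table. The blood list had 1 tested member, Alas2 (0.23 ± 0.52, authors' deposited table), and no set test. The cultures labelled Qk-KO and WT carry the same passage numbers, but the pairing could not be used because the columns hold fitted means. The deposited fit has no passage term either, so its standard errors and p-values leave the pairing out of account.

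**Figure D1:**
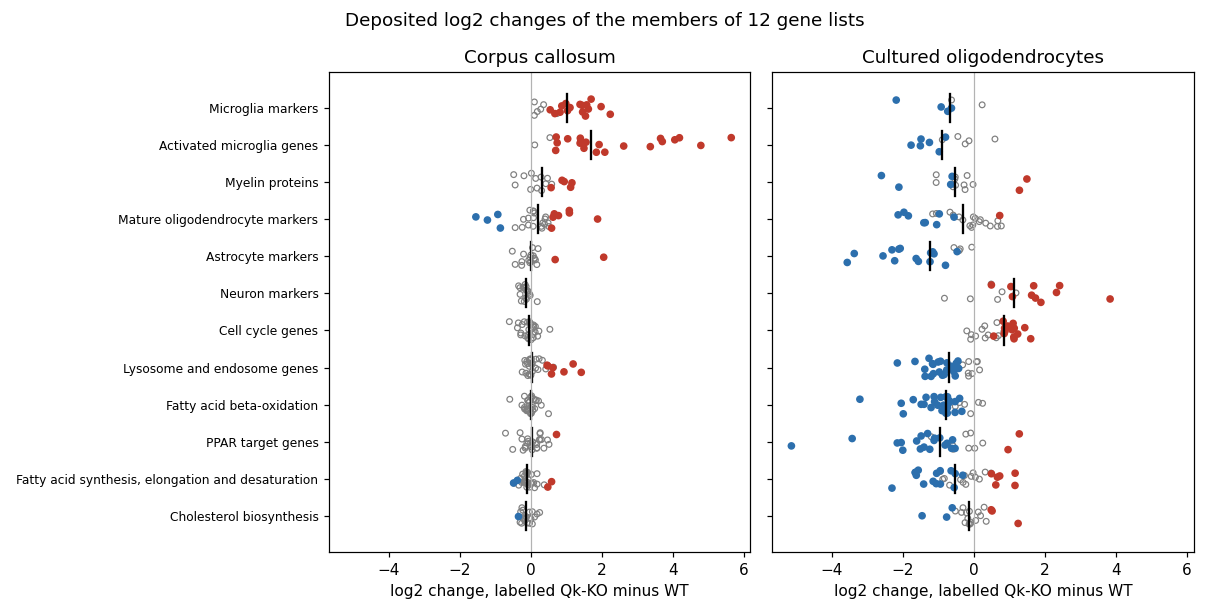
Each point is the log2 change (x axis, labelled Qk-KO minus WT, from the authors' deposited table) of a member of the list on the y axis, filled red (higher) or blue (lower) where the adjusted p is under 0.05 and open otherwise, with a bar at the list median, for callosum (left) and culture (right). Activated microglia genes have a median of 1.70 in callosum, and astrocyte markers a median of -1.24 in culture.

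The last question was whether the changes are shared between tissue and culture. Of 16601 genes tested in both tables, 141 passed in both, 57 in the same direction and 84 in opposite directions. A further 133 callosum calls were not tested in culture and are left out here. The 84 genes were all higher in callosum and lower in culture, where 46.1 were expected from the numbers of calls (Fisher's exact test, adjusted p = 6.3e-08). No gene was lower in callosum and higher in culture, against 4.69 expected (Fisher's exact test, adjusted p = 0.0146). This test takes genes as independent, but genes of 1 cell type or pathway can move together, so its p-values may be too small. Genes lower in both numbered 18, against 5.3 expected (Fisher's exact test, adjusted p = 9.87e-07), and genes higher in both numbered 39, against 40.9 expected (adjusted p = 0.799). Among the shared falls were Scd2, Arsg (-0.87 ± 0.10 and -2.06 ± 0.19 in callosum and culture), Tmem144 (-0.73 ± 0.16 and -3.79 ± 0.34), Prrg1 (-0.92 ± 0.16 and -1.70 ± 0.25), Pls1 (-1.03 ± 0.21 and -1.49 ± 0.33) and Efhd1 (-0.61 ± 0.15 and -1.10 ± 0.22) in the authors' deposited table. Among the shared rises were Tmeff2 (0.74 ± 0.11 and 1.21 ± 0.20), Efnb3 (0.76 ± 0.13 and 1.14 ± 0.22), Adam19 (0.65 ± 0.12 and 1.04 ± 0.20), the glial transcription factor Sox8 (0.83 ± 0.18 and 0.76 ± 0.12), Fam107b (0.66 ± 0.15 and 0.70 ± 0.16) and Ano4 (0.51 ± 0.10 and 0.87 ± 0.21) in the authors' deposited table. Across the 16601 genes, which are not independent replicates, Spearman's rho of the changes was -0.04. By the z test, 3577 genes had different changes in tissue and culture, 1633 higher in culture relative to callosum and 1944 lower; with a Student reference, 0 differed.

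**Figure D2:**
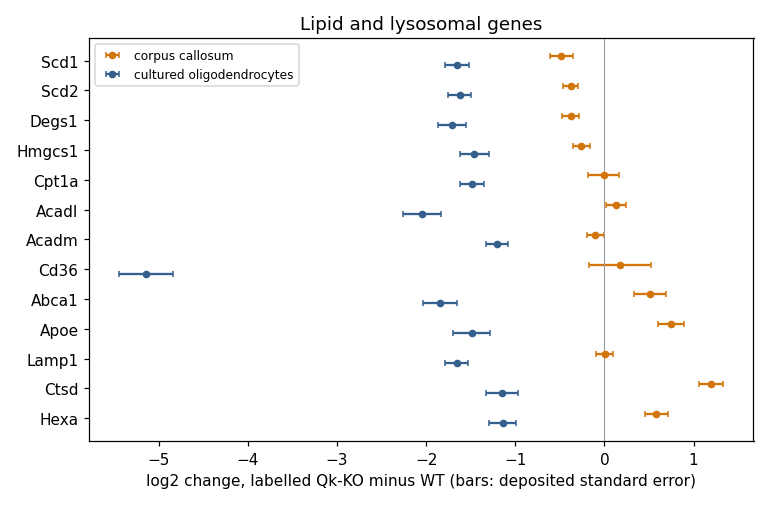
Points give the log2 change (x axis, labelled Qk-KO minus WT) of lipid and lysosomal genes in callosum (orange) and culture (blue), and bars the standard error of the authors' deposited table. Scd1 and Scd2 lie below 0 in both, while Ctsd is at 1.19 in callosum and -1.15 in culture; Hmgcs1, Cpt1a, Acadl, Acadm, Cd36, Abca1 and Lamp1 did not pass in callosum.

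**Figure D3:**
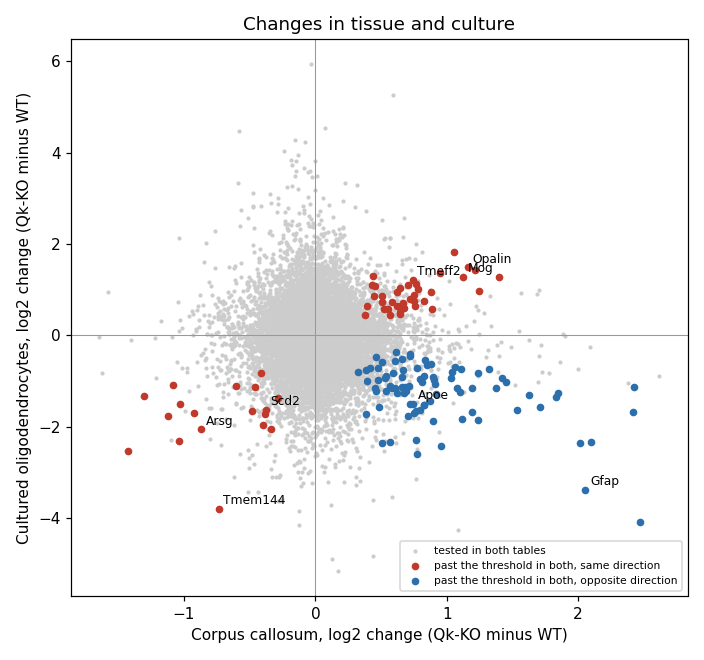
Each point is a gene tested in both tables, with its log2 change (labelled Qk-KO minus WT) in callosum on the x axis and in culture on the y axis; red points passed in both in the same direction (57) and blue points in opposite directions (84).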

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

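The tests of explanations in this part were chosen after the results had been seen, while the z test between the systems was planned for tables without counts. The set test of that difference was also chosen afterwards. The callosum and culture tables share no libraries but differ in age, cell makeup and the agent named in the labels, and these differences stay open for everything below.

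The z test found 3577 genes whose change differed between callosum and culture, and 84 genes passed in both with opposite directions. The fold changes look shrunken toward 0 in each table separately, which the z test does not take into account, so part of these differences may come from it. The strongest differences, culture minus callosum in log2 units, were Srrm3 (4.32 ± 0.26), Hprt (3.33 ± 0.20), Necap2 (-3.31 ± 0.20), Sfxn5 (-3.21 ± 0.20) and Gfap (-5.43 ± 0.34). In the set test of this difference, medians were -1.42 for microglia (6 of 22 members tested in both tables), -2.23 for activated microglia (11 of 22), -1.55 for astrocyte, -0.75 for myelin and -0.63 for mature oligodendrocyte genes. They were -0.88 for lysosome, -0.81 for beta-oxidation, -1.06 for PPAR target, -0.71 for efflux, -0.35 for fatty acid synthesis and -0.17 for phospholipid genes. They were -0.46 for interferon and -0.55 for heat shock genes, and 1.40 for neuron, 0.88 for cell cycle and 0.30 for splicing genes. At a preset correlation of 0.1 the myelin, mature oligodendrocyte, efflux, fatty acid synthesis, phospholipid, cell cycle and splicing lists did not pass (camera adjusted p from 0.0645 to 0.265). The phospholipid and splicing lists did not pass at 0.05 either (0.11 and 0.0698).

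The first pattern is the rise of microglial genes in callosum libraries labelled Qk-KO. For a larger number of microglia with unchanged RNA per cell, P2ry12 (0.18 ± 0.13) and Tmem119 (0.10 ± 0.15, authors' deposited table), which mark microglia in brain, were examined. The higher of their upper 95% limits was 0.44, below the list median of 1.01. Both belong to that list and were named after their low values were seen, so the comparison cannot decide. All 22 tested microglia markers had positive values. For blood left in the tissue, the highest upper 95% limit of the haemoglobin genes was 1.13. This lies below the activated microglia median of 1.70 but not below the microglia marker median of 1.01. The haemoglobin genes therefore argue against blood for the activated list only, as far as they follow the amount of blood. The called members are not themselves neighbours of Qk, since 0% of the 36 lay within 20 Mb of it. Only 326 of all tested genes lie there, so few were to be looked for among 36. Alleles carried along near Qk that act on other genes through a neighbour were not tested and stay open. More microglia, with unchanged or altered RNA per cell, entry of other myeloid cells and a response to the Qk deletion that the labels name stay open.

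The second pattern is lower astrocyte and higher neuron genes in culture. Fewer astrocytes and more neurons, each with unchanged RNA per cell, cannot be told apart from altered expression. With at least 5 CPM, 18 astrocyte markers ranged from -3.57 to -0.39 (Cochran Q of 20.8 per degree of freedom) and 9 neuron markers from -0.10 to 3.84 (Q of 25.9), but markers that other cells share would move less, so this spread alone excludes neither, and no member of either list passed in the other direction. The 40HT treatment without any effect of Qk cannot be told apart from genotype, since 0 of the 3 cultures labelled WT carry 40HT.

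The third pattern is the fall of fatty acid oxidation and PPAR target genes in culture. Expression level or gene length is argued against, since none of 10000 random lists matched on both reached a median as low as -0.77. The lowest was -0.35, and the share is therefore given as 0.01%, the smallest that 10000 lists can resolve. A loss of astrocytes cannot be told apart from a change within cells. Of the 39 lowered members, only Cd36 fell by more than Gjb6, the most lowered astrocyte marker, beyond their standard errors. Cd36 was 1 of 39 members compared without adjustment, and the fold changes look shrunken toward 0. Its fall therefore does not decide the question, and the other members leave such a loss open. The 40HT treatment coincides with genotype here too.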

How the results depend on the processing

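Recentring, the stricter p, the Student reference, the other presets and the rank version were chosen after seeing the data. Most alternatives fixed before the data were examined could not be run, because the library columns hold fitted means: other normalizations by refitting, limma-voom, an own DESeq2 fit, a joint fit of all libraries, sex as a covariate, fry, an estimated correlation, leaving out each replicate, and the count of other splits of the samples. No paired analysis was possible because the columns carry no deviations of single libraries from the genotype means, so the replicate number could not be used as a block. Chance from the choice of groups was therefore not tested.

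The 463 callosum calls became 190 with a minimum change of 2-fold, and the 5003 culture calls became 1890. Without a filter, with at least 5 CPM, without mitochondrial and blood genes, and scaled by library size alone, the counts ranged from 364 to 490 in callosum and from 4104 to 5350 in culture; library size alone was approximated by subtracting -0.02 and -0.08 from all fold changes, and it turned the culture split to 3054 higher and 2296 lower.

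Recentring on the median gene gave 473 and 4967 calls and an adjusted p under 0.01 gave 330 and 3551; the last alternative was a Student reference with 6 and 4 residual degrees of freedom. The Student reference is much stricter, since it treats each deposited standard error as estimated from that gene alone. It left 8 callosum calls, 0 culture calls, 0 genes differing between the systems and 0 shared calls, and it left Qk in culture (log2 0.66) short of the threshold, at an adjusted p of 0.107. At an unadjusted p under 0.05, the deposited table has 1610 callosum and 6548 culture genes. Shared calls in the same direction fell from 57 to 32 at an adjusted p under 0.01. Genes differing between the systems numbered 2915 with at least 5 CPM in both and 84 when opposite calls in both were required. Qk kept its direction in both systems under each alternative run. These left its log2 change as it was or moved all genes by the same small amount, so its direction was not put to a test.

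Of 13 callosum lists, 11 stayed called at a preset correlation of 0.05 and 8 at 0.1; of 15 culture lists, 10 and 9. The rank version called 14 and 15 lists, 12 and 13 of them shared with the main setting. No gene of the naming rule that passed turned its direction, while Slc17a7 in callosum (log2 0.00, without a call) changed sign under library size alone and under recentring. Only these settings alter fold changes, and each moves all genes by the same small amount, so the directions of called genes were not put to a test. The cause of the changes was not tested beyond what each setting removes by construction. Depth limits genes below a mean of 8.08 or 8.52, which have no adjusted p.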

Other observations

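The tests in this part were chosen after seeing the data. Hprt, a gene often used as a reference in expression assays, rose 9.19-fold in cultures labelled Qk-KO (log2 3.20 ± 0.17, authors' deposited table), from 4.06 to 39.4 CPM, but Hprt had -0.13 ± 0.11 in callosum. Necap2 and Sfxn5 fell by 3.21 ± 0.17 and 3.24 ± 0.18 in culture and had 0.10 ± 0.11 and -0.03 ± 0.09 in callosum in the authors' deposited table. Some genes of the activated microglia list that other cells also express went opposite ways: Apoe, Axl and Csf1 rose in callosum by 0.74 ± 0.15, 0.70 ± 0.12 and 1.04 ± 0.15 and fell in culture by 1.49 ± 0.20, 1.77 ± 0.17 and 0.80 ± 0.14 in the authors' deposited table.

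A hypothesis for the neuronal rise in culture is that lower Rest, which encodes a repressor of neuronal genes, may release its targets. Rest fell by 0.52 ± 0.13 log2 units in culture (adjusted p = 2.87e-04, authors' deposited table) and had 0.22 ± 0.20 in callosum. A list of 46 genes described as REST targets was written from textbook knowledge after some of the culture changes had been seen, and 26 of its 38 tested members rose, with a median of 1.61, which is 0.54 above the other neuron markers. Much of that difference rests on genes known beforehand to be high: without the 11 members that were already on a fixed list or had been seen, 17 of 27 tested members rose and 1 fell, among them Stx1a (2.60 ± 0.23), Chga (2.50 ± 0.22) and Unc13a (2.17 ± 0.12) of the authors' deposited table, with a median of 1.16. This shorter list, made after the result of the longer one was known, lay 0.091 above the other neuron markers (permutation p = 0.72, two-sided). Release of REST targets cannot be told apart from a rise of neuronal genes in general, because the difference between the 2 groups did not pass the test.

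A second hypothesis is that callosum libraries may hold uneven amounts of neighbouring tissue. Standard errors of striatal and choroid plexus markers had medians of 0.42 and 0.34, against 0.13 and 0.17 for lists matched on mean count, and both lay above 100% of 10000 such lists. Cortical (0.27 against 0.12) and fibroblast markers (0.31 against 0.18) also lay above 100% of matched lists, and microglia (0.18 against 0.13), astrocyte (0.15 against 0.12) and neuron markers (0.15 against 0.11) above most. Mature oligodendrocyte markers (0.18 against 0.12) and myelin genes (0.16 against 0.12) lay above most as well. Cortex and meninges also lie near the callosum, and the excess was smaller for the microglia, astrocyte, neuron, oligodendrocyte and myelin lists. Every list examined showed some excess, so an excess as such is not particular to neighbouring tissue. In the same table, 156 genes have a fold change without a p-value, among them Slc17a6, Prkcd and Ntng1, which were chosen after their values were seen and are known from thalamic neurons. They also include 4 of 4 Y-linked genes checked, as do the 20 such genes of the culture table, so libraries of differing sex may be behind some of them, which was not tested.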
